A study of Mus musculus with 16 samples.

How the data were processed

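RNA of whole liver or liver tumour tissue of male mice, 16 months old, was extracted with Trizol, amplified to single-stranded cDNA by an isothermal whole-transcriptome method and labelled with biotin, per the labels' protocols. It was hybridised to one-colour oligonucleotide arrays, 1 array per sample. The deposited values are log2 expression values, and RMA and Partek are named in the submitters' processing notes, without versions, roles or order. The chip model, the probe set definition and the genome build are not given in the sources used here. Identifiers are a gene number and a suffix, with 1 probe set per gene. The authors' values span 1.47 to 12.9 with nearly equal medians on every array; they are not centred per gene. RMA adjusts background, equalises the distributions of arrays and fits 1 value per probe set, so small global shifts between tissues are removed and changes of dim probe sets are compressed.

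Of 24479 probe sets, 23281 had 1 gene symbol in the platform annotation, 0 had several and 1198 had none there and stayed out of the named tests. For the 2 symbols with 2 probe sets the one with the higher mean was used, which left 23279 genes. Samples were assigned from their titles: 3 controls (mice 10, 11 and 12), adjacent liver of mice 121, 124, 123, 1931 and 81, and tumours of mice 121, 90, 124, 123, 93 and 81, with 3 tumours of mouse 121. The titles number the animals, so p-values of single genes measure the spread between mice. Whether adjacent liver 1931 and tumour 93 share a mouse is not known, and they were treated as different mice. The labels give no scan date, slide or other batch, so no batch could be tested.

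The 3 tumours of mouse 121 were averaged first. All 3 groups were fitted together in limma (version 3.58.1, R 4.3.3) with lmFit and eBayes with an intensity trend, without a block, and p-values were adjusted by Benjamini-Hochberg over all 23279 genes; a gene passed at an adjusted p under 0.05. SE is that of the moderated fit. For Axin1, Glul, Axin2, Lgr5 and Tbx3, two-sided exact permutation tests of the difference of group means were added after the data were seen and adjusted over 15 tests. Before the data were examined, 31 gene lists (pathways, liver zones, sex-biased genes and markers of other cell types; 705 entries, of which 648 were used here) were written from textbook knowledge; some genes stand in several lists, such as Prom1 in the fetal, female-biased and cholangiocyte lists. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry as alternatives, and Benjamini-Hochberg over the 31 lists. Camera compares members with the other genes, so its p-values rest on the correlation between members and not on the spread between mice alone. The estimated correlations ran from 0.0405 to 0.714, all above the preset value. For members, an adjusted p over the list alone was computed beside that over all genes.

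The rule for named genes was fixed before the data were examined. Per comparison it takes Axin1, Glul, Axin2, Lgr5 and Tbx3; the 8 genes with the largest increase and the 8 with the largest decrease among genes past the threshold whose groups do not overlap, leaving out predicted or clone-named genes and receptor families; and of each list up to 4 members past the threshold, or else the first 2 present. Genes named outside it are marked in the text as chosen after their values were seen.

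Mouse numbers in the titles pair 4 tumours with adjacent liver of the same animal (121, 124, 123 and 81). Deviations from the group means of such pairs correlated at 0.0789 on average (0.0349 to 0.0998), and those of pairs treated as different mice at -0.0116 (-0.328 to 0.317). The highest of these, 0.317, is tumour 93 with adjacent liver 1931, which lay above every pair known to share a mouse. Since pairs known to share a mouse lay within the range of the others, the correlation does not tell whether these 2 are 1 animal. The fits with the mouse as a random block over all arrays, and as a fixed block in the 4 paired mice, were alternatives. The random block entered the 3 tumours of mouse 121 separately, at an estimated within-mouse correlation of 0.0732. Other alternatives fixed before the data were examined were quantile normalization or median centring on top of the deposited values, a filter that keeps the 12864 genes above a log2 value of 4.43 (the median of all values) on at least 3 arrays, the mean of probe sets, all probe sets, no intensity trend, array weights per group, only the 2 groups compared, all 8 tumours as separate values, the unnumbered tumour of mouse 121 only, and each mouse left out in turn. Control 10 was singled out after the data were seen, although its omission was among those planned. List members with each mouse left out were also added after the data were seen. For tumour 93, 18 genes were tested first and larger gene sets, then counts gene by gene, were added after the earlier results were seen; all are reported.

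The gene and list tests were run on simulated normal data with the group sizes, gene means and gene-wise spreads of these samples, with 23279 genes in each comparison. For true differences of 1, 2 and 3 log2 units, recovery was 56.7%, 95.5% and 100% for tumour against control, 80.6%, 97.0% and 98.5% for tumour against adjacent liver, and 74.6%, 98.5% and 98.5% for adjacent liver against control. Each comparison held 67, 67 and 66 genes changed by these sizes beside 1 shifted list, and 7, 10 and 10 unchanged genes were called. Many changed genes ease the adjusted threshold. Recovery can therefore be lower in the real fits, where 6, 36 and 0 genes passed. The list that was shifted was called in each comparison and 0 other lists were. Genes were drawn independently and with 1 spread per gene for all groups, whereas the estimated correlations of the real lists reached 0.714. The simulation therefore does not show how often lists are called falsely in these data. Arrays carry no read depth, and their number sets the precision. No genomic coordinates are given because the build behind the probe sets is not stated.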

Results

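Liver RNA of male mice aged 16 months was profiled on one-colour oligonucleotide arrays, 1 array per sample. Axin1-deleted mice carried a conditional Axin1 allele and a Cre recombinase that is active in embryonic hepatocytes, and they develop liver tumours with age. Axin1 encodes a scaffold of the complex that marks beta-catenin, the effector of Wnt signalling, for degradation. The 16 arrays held liver of 3 control mice without the deletion, non-tumoral liver next to tumours of 5 Axin1-deleted mice, and 8 tumours of 6 Axin1-deleted mice. Mouse 121 gave 3 tumours, whose values were averaged so that each mouse counted once, and 4 mice gave both a tumour and adjacent liver. The medians of the arrays lay between 4.37 and 4.50 on the log2 scale, and the number of arrays limits the precision of every value. Tumour arrays correlated with one another, across genes, at r between 0.945 and 0.983, and adjacent livers at r between 0.976 and 0.989; genes are not independent replicates. The first principal component held 31.5% of the variance, and along it tumours spread from -57.7 to 13.8 whereas control and adjacent livers lay between 4.53 and 33.8.

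Axin1 (Entrez gene 12005), the deleted gene, was lower in each of the 13 arrays of deleted mice than in any control. Its log2 value was 5.26 ± 0.20 (SD, n = 3) in control liver, 4.21 ± 0.21 (SD, n = 5) in adjacent liver and 4.44 ± 0.31 (SD, n = 6) in tumours. Against control the log2 difference was -1.06 (SE 0.18) in adjacent liver and -0.83 (SE 0.18) in tumours. Over all genes limma gave adjusted p = 0.255 for adjacent liver and adjusted p = 0.102 for tumours, neither past the threshold. Adjusted over the list alone, the 12 genes of the beta-catenin destruction complex, Axin1 fell in both (adjusted p = 0.000527 and adjusted p = 0.00431). In two-sided exact permutation tests the p-values were 0.0179 and 0.0119, the smallest that these group sizes allow, or 0.065 and 0.0595 after adjustment over 15 tests. Tumour and adjacent liver did not differ detectably in Axin1 (log2 difference 0.23, exact p = 0.186). The exons that the probe set covers are not given in the sources used here, and non-hepatocytes in the tissue keep the gene, so the value is no measure of how much of the gene was deleted, and a probe outside the deleted exons would not test the deletion.

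**Figure D1:**
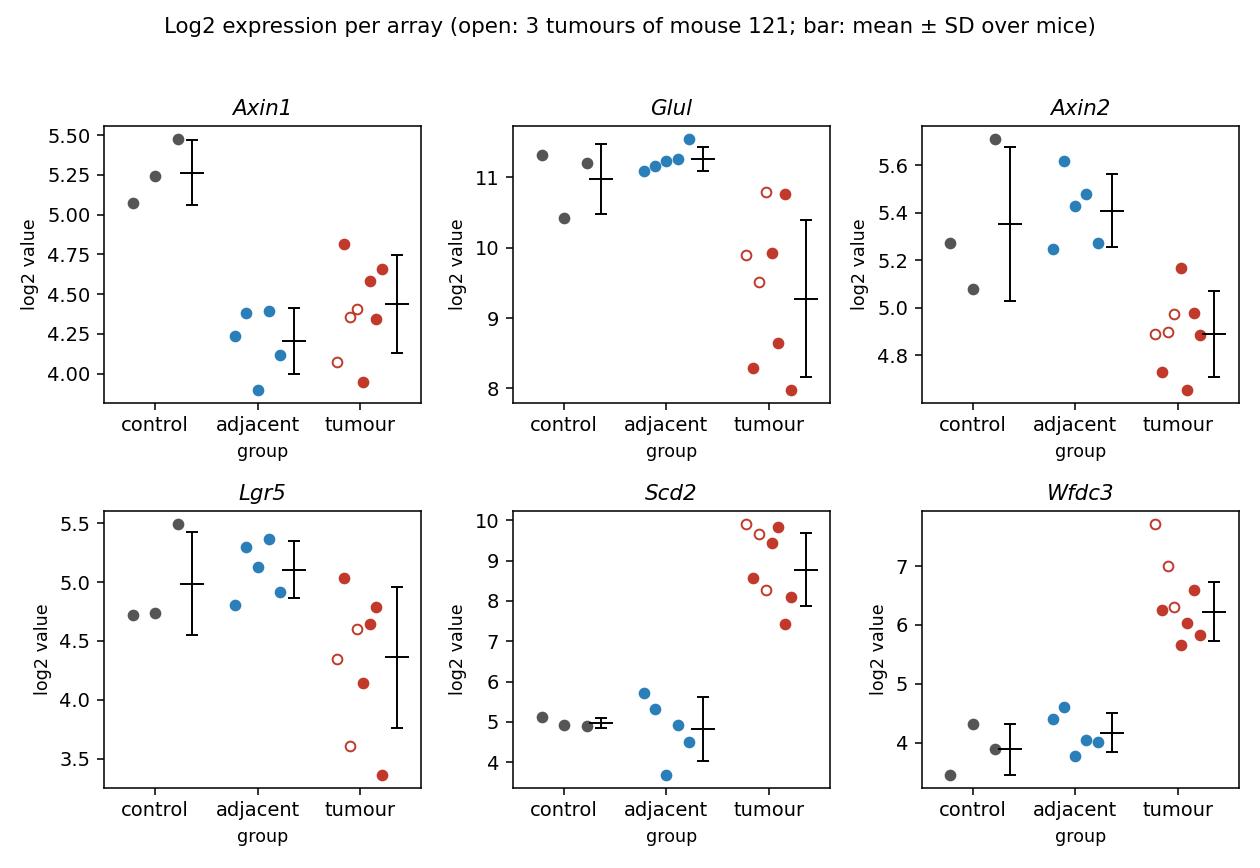
Log2 expression (y axis) of 6 genes on the 16 arrays, by group (x axis); open circles are the 3 tumours of mouse 121 and the black bars give mean ± SD over mice (3 control, 5 adjacent, 6 tumour). Axin1 was 3.90 to 4.81 in deleted mice and 5.07 to 5.48 in controls, while Scd2 and Wfdc3 were higher in each tumour than in any non-tumoral liver.

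The first comparison asked what distinguishes the non-tumoral liver of tumour-bearing deleted mice from control liver. Genes of fatty acid oxidation that respond to peroxisome proliferators were higher in adjacent liver, with a median log2 change of 0.48 over 21 members (camera, adjusted p = 1.56e-11, and adjusted p = 0.82 with an estimated correlation). Of this list Cpt1a, which admits fatty acids to mitochondria, was at 0.56 (SE 0.18) and Cpt2 at 0.21 (SE 0.36), neither past the threshold. Cyp4a14, a fatty acid hydroxylase, had the largest difference of the list, 3.21 (SE 0.95, adjusted p = 0.058 over the list alone), not past the threshold, and was named after its value was seen. Fatty acid synthesis genes were slightly higher (18 members, median 0.24, adjusted p = 0.0385), and male-biased liver genes (20 members, median -0.20, adjusted p = 0.0311) and neutrophil markers (18 members, median -0.40, adjusted p = 2.42e-05) were lower. These 3 lists had adjusted p = 0.989, 0.989 and 0.836 with an estimated correlation. Single genes of these lists did not pass: S100a8, a neutrophil alarmin, was at -1.36 (SE 1.02).

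Over all 23279 genes, none passed the threshold between adjacent and control liver (limma, 0 genes at an adjusted p under 0.05, 1059 at an unadjusted p under 0.05, smallest adjusted p 0.146). The 2 groups did not overlap in 4.22% of genes, where chance gives 3.57%. Markers of Wnt activity in pericentral hepatocytes did not pass either. The log2 difference was 0.28 for Glul, glutamine synthetase (SE 0.51, exact p = 0.357), and 0.05 for Axin2 (SE 0.16, exact p = 0.768). It was 0.12 for Lgr5 (SE 0.31, exact p = 0.661) and -0.02 for Tbx3 (SE 0.32, exact p = 0.946). The other 27 lists had medians between -0.29 and 0.13 and adjusted p of 0.0766 or more. In 6 of them the median differed in sign from the mean or the test: periportal genes, cell cycle, cholangiocyte, matrix remodelling, erythroid and pancreas, adipose and muscle markers. The neutrophil list lost its call without control 10 (adjusted p = 0.758), an array high in inflammatory genes (S100a8 at 8.71, against 3.54 and 3.34 in the other controls). The male-biased list lost its call without control 11 (0.694), control 12 (0.0602), adjacent 121 (0.0674) or adjacent 81 (0.145). Fatty acid synthesis lost its call without control 10 (0.0821), control 12 (0.273), adjacent 1931 (0.214) or adjacent 81 (0.145).

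The second comparison asked what distinguishes tumours from the liver around them. Scd2 (Entrez gene 20250), a stearoyl-CoA desaturase, was 15.4-fold higher in tumours, at 8.77 ± 0.91 (SD, n = 6) against 4.83 ± 0.79 (SD, n = 5) in adjacent liver (log2 change 3.95, SE 0.42, adjusted p = 0.00277), and higher in 6 of 6 tumour mice. Cbr3, a carbonyl reductase, rose by 3.52 (SE 0.62, adjusted p = 0.0464), Anxa2, a membrane-binding annexin, by 2.65 (SE 0.46) and Nid1, a basement membrane glycoprotein, by 2.25 (SE 0.40). Wfdc3 (Entrez gene 71856) rose by 2.06 (SE 0.24, adjusted p = 0.00483), Pygb, a glycogen phosphorylase, by 1.98 (SE 0.26, adjusted p = 0.00863), Fkbp11 by 1.96 (SE 0.36) and Mfge8, a secreted bridging protein, by 1.82 (SE 0.29). Casd1 fell by 1.01 (SE 0.18) and Zfp445, a zinc finger protein, fell by 0.85 (SE 0.15); the third gene that fell, 0610043K17Rik, changed by -1.24 and was named after its value was seen.

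In total 36 genes differed between tumour and adjacent liver with limma at an adjusted p under 0.05, of which 33 rose and 3 fell, 28 and 2 of them at least 2-fold; 3556 genes had an unadjusted p under 0.05. The groups did not overlap in 33 of the 36, and over all genes in 2.23%, where chance gives 0.433%. With the mouse as a random replicate block over all arrays the count was 206, and with the mouse as a fixed block in the 4 paired mice it was 0 (Scd2, adjusted p = 0.0885). The random block entered the 3 tumours of mouse 121 separately at a within-mouse correlation of 0.0732, so they counted almost as separate mice. With 8 tumours as separate values and no block the count was 87. The count was 743 without tumour 93 and 123 without tumour 90, whereas it was 5 without adjacent 123, adjacent 124 or tumour 123. It was 6 without adjacent 1931, 7 without adjacent 81, 8 without control 11, 9 without the tumours of mouse 121, 15 without control 10, 18 without control 12 and 19 without tumour 81. Scd2, Wfdc3 and Pygb passed in each of these 14 omissions, whereas Mfge8 missed in 7, Anxa2 in 8, Nid1 and Fkbp11 in 10, Cbr3 in 11, and Casd1, Zfp445 and Sox4 in 12.

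Among the 31 fixed gene lists, 21 differed between tumour and adjacent liver by camera with a preset correlation of 0.01 (14 higher, 7 lower), and 0 with an estimated correlation (smallest adjusted p 0.154). The alternative fry, which asks whether a list moves on balance one way, called 4: fetal and tumour markers, cell cycle, Wnt targets and p53 targets. Over all genes tested only Scd2 and Sox4 of the list members passed, so the counts of members below are adjusted over the list alone. Where a list had no member past the threshold over all genes, the first 2 members were fixed as examples, and the others named were chosen after their values were seen.

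Proliferation and fetal liver genes were higher in tumours. Of 34 cell cycle and mitosis genes 28 rose (median log2 change 0.95, adjusted p = 5.1e-25), among them Mki67 (1.42, SE 0.37), Top2a (1.87, SE 0.51) and Rrm2, a subunit of ribonucleotide reductase (0.98, SE 0.25). Of 28 fetal liver and liver tumour markers 15 rose (median 1.21, adjusted p = 1.72e-14), among them Scd2, the transcription factor Sox4 (1.36, SE 0.25), the imprinted RNA H19 (3.20, SE 0.82) and Spink1 (3.42, SE 0.69). Tumour 90 stood apart in the cell cycle list, with a mean of -0.13 against the control mean, where the other tumour arrays lay at 0.59 to 1.67. Afp, alpha-fetoprotein, rose by 1.41 (SE 0.56), largely through tumour 123 (0.82 without it, adjusted p = 0.0115 over the list alone), whereas Gpc3, glypican-3, did not pass (2.21, SE 1.06, adjusted p = 0.098 over the list alone). The adjusted p of both lists was 0.154 with an estimated correlation.

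Stress response genes were higher as well. Of 18 p53 targets 10 rose and 1 fell (median 0.44, adjusted p = 0.000122), including Cdkn1a, a cell cycle inhibitor (1.30, SE 0.48), and Mdm2 (0.32, SE 0.12). Of 18 targets of NRF2, the regulator of antioxidant genes, 4 rose (median 0.60, adjusted p = 1.17e-07), including the quinone reductase Nqo1 (1.70, SE 0.43) and the cystine transporter Slc7a11 (4.01, SE 1.04); Gclc was at 0.60 (SE 0.27), not past the threshold. Tumour 124 stood apart in the NRF2 list, with a mean of 2.10 against the control mean, where the other tumour arrays lay at 0.35 to 1.06; without it the list had adjusted p = 1.36e-05. The glycolysis and hypoxia list was higher (21 members, median 0.32, adjusted p = 0.00133), with Ndrg1 the member that rose (1.43, SE 0.32) and Hk1 (0.20, SE 0.22) and Hk2 (0.60, SE 0.42) not past the threshold. These 3 lists had adjusted p = 0.154, 0.158 and 0.389 with an estimated correlation.

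Lists of 2 further signalling pathways were higher by small amounts. The Notch list had a median of 0.23 over 20 members (adjusted p = 6.76e-05) with 0 past the threshold, Hes1 at 0.63 (SE 0.40) and Hey1 at 0.23 (SE 0.13). The YAP/TAZ list had a median of 0.30 over 24 members (adjusted p = 0.000426), of which 4 rose, led by Igfbp3 (2.34, SE 0.58), while Ccn2 (0.48, SE 0.28) and Ccn1 (0.39, SE 0.32) did not pass. The adjusted p was 0.154 for each with an estimated correlation.

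Targets of Wnt signalling in liver were lower in tumours. Of 21 targets 9 fell and 0 rose (median -0.52, adjusted p = 2.47e-06, and adjusted p = 0.154 with an estimated correlation). Glul changed by -1.98 (SE 0.42; 9.28 ± 1.12, SD, n = 6, against 11.26 ± 0.17, SD, n = 5), Axin2, a feedback inhibitor of the pathway, by -0.52 (SE 0.13), Lgr5, an R-spondin receptor, by -0.74 (SE 0.26) and the glutamate transporter Slc1a2 by -3.07 (SE 0.59); each was lower in 6 of 6 tumour mice than the adjacent mean. Over all genes Glul and Axin2 missed the threshold (adjusted p = 0.0634 and 0.0896), and Glul passed with the mouse as a random block (0.0472) but not as a fixed block (0.152). By exact permutation test, which exchanges tumour and adjacent values freely and so ignores that 4 mice gave both, the two-sided p was 0.00433 for Glul and for Axin2 (0.0325 adjusted over 15 tests), 0.026 for Lgr5 (0.065) and 0.0823 for Tbx3 (0.139; log2 change -0.62, SE 0.27). Periportal hepatocyte genes, which mark the opposite zone of the lobule, went both ways: 2 rose and 2 fell of 16 (median -0.36, adjusted p = 0.345), with Arg1 at -0.39 (SE 0.27) and Cyp2f2 at -2.25 (SE 1.10), neither past the threshold. In the destruction complex list 1 of 12 members fell, Axin2, and the median was 0.06 (adjusted p = 0.45).

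Lists of bile acid genes, male-biased genes and urea cycle genes were lower in tumours, and female-biased genes were higher. Of 21 genes of bile acid synthesis and transport 9 fell and 2 rose (median -0.94, adjusted p = 0.000401), with Cyp8b1, the sterol 12-hydroxylase, at -2.19 (SE 0.77) and the exporter Abcc4 at 2.99 (SE 0.56); Cyp7a1, which opens the pathway, did not pass (-1.35, SE 0.89). Of 20 male-biased liver genes 11 fell and 1 rose (median -1.40, adjusted p = 2.93e-06), such as Cyp4a12a (-2.99, SE 1.04) and Cyp4a12b (-2.01, SE 0.67). Of 22 female-biased genes 3 rose and 1 fell (median 0.48, adjusted p = 0.00105), with Cyp2a4 at 2.91 (SE 0.66). Sult2a1 (0.44, SE 0.44) and Sult3a1 (-0.21, SE 0.13) did not pass. Of 20 urea cycle and amino acid genes 3 fell (median -0.45, adjusted p = 7.12e-06); Cps1 (-0.25, SE 0.14) and Otc (-0.64, SE 0.23) did not pass. The adjusted p of these 4 lists was 0.389, 0.301, 0.154 and 0.365 with an estimated correlation.

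Of 21 peroxisome proliferator and fatty acid oxidation genes 4 fell and 1 rose (median -0.32, adjusted p = 0.00171), with Cyp4a14 at -3.27 (SE 0.79) and Cpt1a (-0.20, SE 0.15) and Cpt2 (-0.60, SE 0.30) not past the threshold. Fatty acid synthesis genes were lower (18 members, 0 past the threshold, median -0.36, adjusted p = 0.00708), with Fasn at -0.28 (SE 0.23) and Acaca at -0.06 (SE 0.16). Both lists were higher in adjacent liver than in control liver (medians 0.48 and 0.24). Tumours against control liver had medians of 0.08 and -0.14, so these falls are relative to adjacent liver. Cholesterol synthesis genes were higher (19 members, 2 rose, median 0.18, adjusted p = 0.0387; Sqle 1.18, SE 0.34; Hmgcs1 0.29, SE 0.42, not past the threshold). With an estimated correlation the adjusted p was 0.454, 0.471 and 0.644. Secreted hepatocyte proteins and hepatocyte transcription factors had a median of -0.10 (22 members, 0 past the threshold, adjusted p = 0.00708, and adjusted p = 0.389 with an estimated correlation), with Alb at 0.01 (SE 0.11) and Ttr at -0.12 (SE 0.08). The secreted protein and fatty acid synthesis lists lost their calls without tumour 81 (adjusted p = 0.142 for each). Cholesterol synthesis lost its call without tumour 121 (0.0722), tumour 124 (0.315), tumour 123 (0.096), tumour 93 (0.268), adjacent 121 (0.292), adjacent 124 (0.114) or adjacent 81 (0.104).

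Among markers of other cell types, the stellate cell and fibroblast list and the cholangiocyte list were higher in tumours. Of 24 stellate cell and fibroblast markers 9 rose and 2 fell (median 0.53, adjusted p = 3.08e-05), with the collagens Col1a1 (1.25, SE 0.38) and Col1a2 (1.09, SE 0.33) higher and Lrat, which stores retinol in quiescent stellate cells, lower (-1.06, SE 0.30). Of 20 matrix remodelling genes 12 rose (median 0.75, adjusted p = 5.95e-11), led by Mmp12 (2.53, SE 0.59), while Mmp2 (0.25, SE 0.24) and Mmp9 (0.09, SE 0.20) did not pass. Of 19 cholangiocyte markers 4 rose (median 0.25, adjusted p = 0.00153), Sox9 by 0.89 (SE 0.28), but Krt19 (-0.05, SE 0.25) and Krt7 (0.33, SE 0.31) did not. With an estimated correlation the adjusted p was 0.311, 0.154 and 0.154. The endothelial list went both ways, with 5 of 25 members higher and 8 lower (median -0.10, adjusted p = 0.887). The members that rose were Pecam1 (1.03, SE 0.26), Cdh5 (0.84, SE 0.29), Emcn (1.70, SE 0.33), Cd34 (1.67, SE 0.33) and Tie1 (0.47, SE 0.17). Those that fell were Stab2 (-1.31, SE 0.39), Clec4g (-2.41, SE 0.68), Rspo3 (-1.36, SE 0.33), Oit3, Bmp2, Mrc1, Gata4 and Fcgr2b.

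Antigen presentation (16 members, median 0.22, adjusted p = 0.00175; H2-K1 -0.07, SE 0.14; H2-D1 0.15, SE 0.17) and interferon-stimulated genes (22 members, median 0.25, adjusted p = 0.0334; Isg15 0.43, SE 0.47; Ifit1 0.21, SE 0.51) were higher with 0 members past the threshold, and had adjusted p = 0.471 and 0.644 with an estimated correlation. The interferon list lost its call without tumour 81 (0.631), tumour 121 (0.0946), adjacent 123 (0.239), adjacent 124 (0.114) or adjacent 1931 (0.0908). Of 24 Kupffer cell and macrophage markers 2 rose (median 0.30, adjusted p = 0.17), Cd9 and Ms4a7, while Clec4f (-1.86, SE 0.59) and Vsig4 (-2.52, SE 0.91), markers of resident Kupffer cells, did not pass. The remaining lists did not pass: T and NK cells (median -0.00040 with a mean of 0.03, adjusted p = 0.931), B and plasma cells (-0.10, 0.18), neutrophils (0.08, 0.18), acute phase (-0.10, 0.717), erythroid (-0.13, 0.283; 1 rose, Tfrc) and pancreas, adipose and muscle markers (0.01, 0.134; 1 rose, Cela1).

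**Figure D2:**
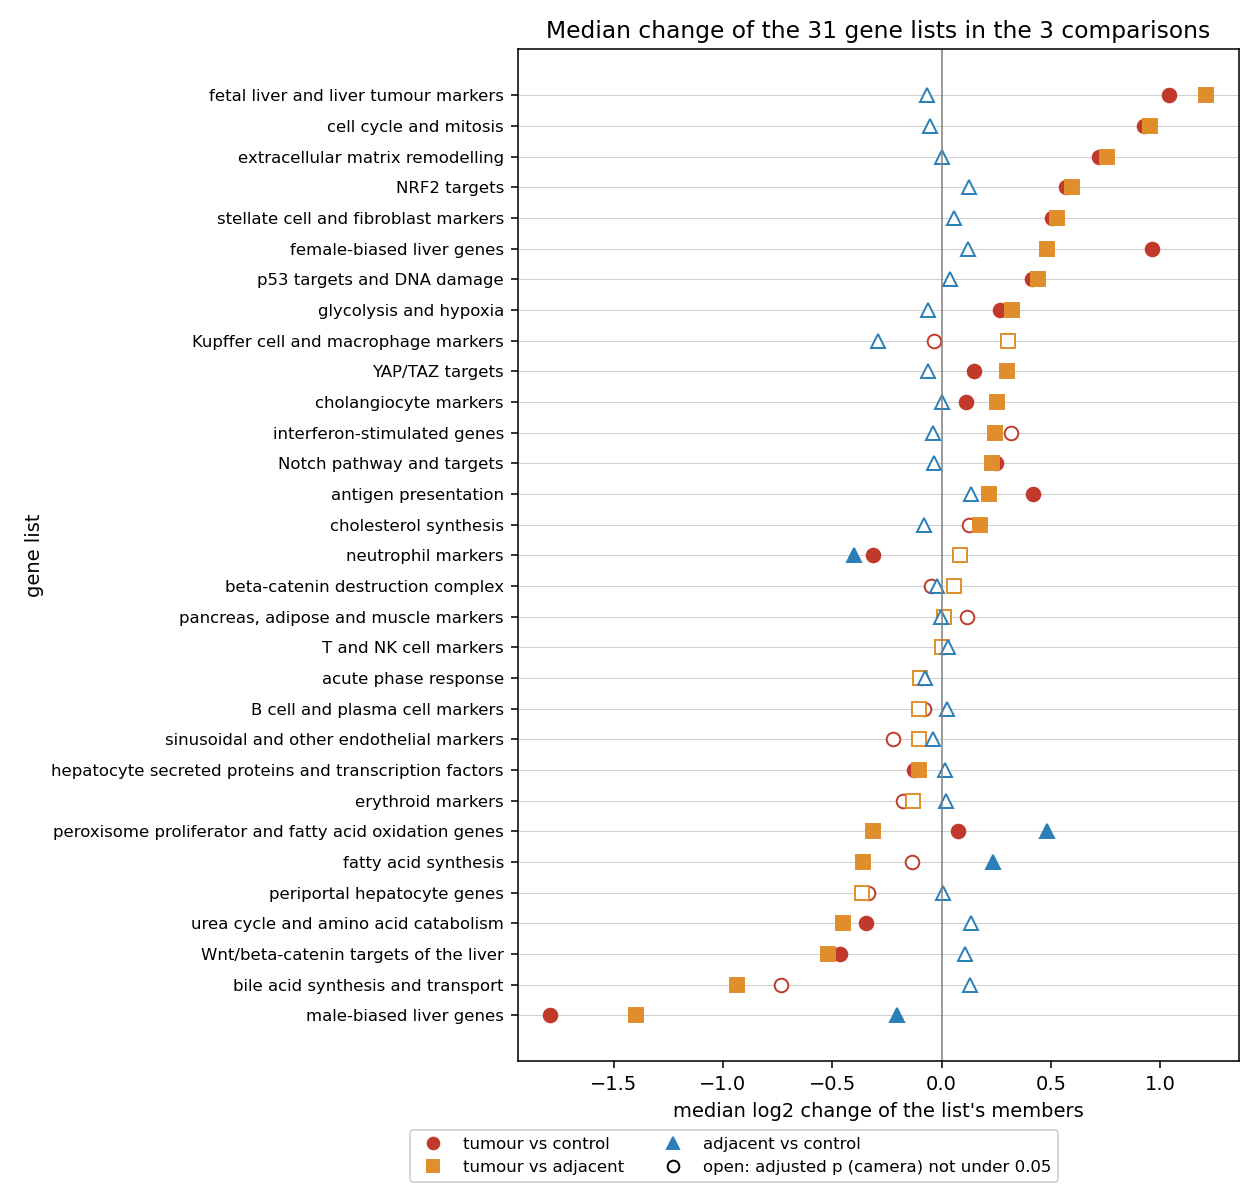
Median log2 change (x axis) of the members of each of the 31 gene lists (y axis) in the 3 comparisons, with filled symbols where camera gave an adjusted p under 0.05. Both tumour comparisons ran from male-biased genes (-1.79 and -1.40) to fetal liver and liver tumour markers (1.04 and 1.21), and the adjacent liver comparison stayed between -0.40 and 0.48.

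The third comparison set tumours against the livers of control mice. Scd2 was 13.8-fold higher in tumours (log2 change 3.79, SE 0.48, adjusted p = 0.0104; control 4.98 ± 0.12, SD, n = 3), Wfdc3 rose by 2.35 (SE 0.28, adjusted p = 0.0104) and Prss8 (Entrez gene 76560), a membrane-anchored serine protease, by 1.43 (SE 0.20, adjusted p = 0.0191). Colec10 (Entrez gene 239447), a collectin, fell by 2.07 (SE 0.31, adjusted p = 0.0385) and Sult5a1 (Entrez gene 57429), a sulfotransferase, fell by 1.97 (SE 0.30, adjusted p = 0.0385). Sult5a1 was low in adjacent liver too, at 4.01 to 5.49, where tumours lay at 3.88 to 5.20 and controls at 6.24 to 6.73. Its difference from control is thus not particular to tumours, although it did not pass between adjacent and control liver. The sixth gene past the threshold, Vmn2r25, fell by 0.50 and lay near the lower end of the values (2.16 in tumours); it was named after its value was seen. All 6 genes differed in 6 of 6 tumour mice without overlap between groups.

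These were the 6 genes past an adjusted p under 0.05 with limma (3 rose and 3 fell), and 2917 had an unadjusted p under 0.05; groups did not overlap in 5.18% of genes, where chance gives 2.38%. With the mouse as a random replicate block, which entered the 3 tumours of mouse 121 separately, the count was 24. The count was 242 without tumour 93, 76 without tumour 90 and 10 without control 10, but 3 without the tumours of mouse 121 or tumour 123, and 2 without control 11. It was 0 without control 12, where Scd2 and Wfdc3 had adjusted p = 0.0622 and 0.0598; without control 11 Scd2 had 0.0645. Prss8 missed in 5 of the 14 omissions, Sult5a1 in 9 and Colec10 in 10.

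Of the 31 lists, 18 differed between tumours and control liver by camera (13 higher, 5 lower), 0 with an estimated correlation (smallest adjusted p 0.109), and 2 by fry, fetal and tumour markers and p53 targets. Over all genes Scd2 was the list member past the threshold; member counts are again adjusted over the list alone, and members beyond the fixed examples were chosen after their values were seen. Cell cycle genes (26 of 34 rose, median 0.93, adjusted p = 9.5e-23; Mki67 1.29, SE 0.43; Top2a 1.65, SE 0.59) and fetal liver and tumour markers (11 of 28 rose, median 1.04, adjusted p = 3.69e-13; Ly6d 4.45, SE 0.76) were higher; tumour 90 again did not share the rise in cell cycle genes. Without control 12 Top2a was at 1.08 (adjusted p = 0.16 over the list alone). So were NRF2 targets (8 of 18 rose, median 0.57, adjusted p = 9.07e-08; Nqo1 2.31, SE 0.51; Gclc 0.53, SE 0.32, not past the threshold) and p53 targets (5 of 18 rose, median 0.41, adjusted p = 4.3e-06; Cdkn1a 2.17, SE 0.56; Mdm2 0.20, SE 0.14, not past the threshold). Their adjusted p was 0.216, 0.109, 0.216 and 0.109 with an estimated correlation.

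Matrix remodelling genes (6 of 20 rose, median 0.72, adjusted p = 3.45e-09; Mmp12 3.22, SE 0.69) and stellate cell and fibroblast markers (10 of 24 rose and 3 fell, median 0.50, adjusted p = 1.36e-05; Col1a1 1.31, SE 0.44; Col1a2 1.13, SE 0.39) were higher, with adjusted p = 0.216 and 0.275 with an estimated correlation. Male-biased genes were lower (8 of 20 fell, median -1.79, adjusted p = 8.97e-11; Elovl3 -3.82, SE 1.34; Cyp4a12a -2.68, SE 1.22, not past the threshold) and female-biased genes higher (5 of 22 rose, median 0.96, adjusted p = 1.42e-05; Cyp2a4 4.11, SE 0.77), with adjusted p = 0.216 and 0.109 with an estimated correlation. Wnt targets were lower (4 of 21 fell, median -0.46, adjusted p = 0.00107, and adjusted p = 0.275 with an estimated correlation), with Glul at -1.71 (SE 0.49; exact p = 0.0357), Axin2 at -0.47 (SE 0.15; exact p = 0.0238), Lgr5 at -0.63 (SE 0.30; exact p = 0.19) and Tbx3 at -0.65 (SE 0.31; exact p = 0.0833). Without control 12 Axin2 was at -0.29 (adjusted p = 0.337 over the list alone). After adjustment over 15 tests the exact p-values were 0.0765, 0.065, 0.259 and 0.139. Urea cycle and amino acid genes were lower too (1 of 20 fell, median -0.35, adjusted p = 0.000912, and adjusted p = 0.507 with an estimated correlation).

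The Notch (median 0.25 over 20 members, adjusted p = 0.00036; Hes1 0.43, SE 0.47; Hey1 0.30, SE 0.15) and YAP/TAZ lists (median 0.15 over 24 members, adjusted p = 0.00574; Ccn2 0.86, SE 0.33; Ccn1 0.58, SE 0.37) were higher with 0 members past the threshold, and had adjusted p = 0.216 and 0.275 with an estimated correlation. Lists whose call rested on single arrays were antigen presentation (median 0.42, adjusted p = 0.000518, 0.122 without control 12), glycolysis and hypoxia (0.27, adjusted p = 0.00433, 0.0723 without tumour 81), cholangiocyte markers (0.11, adjusted p = 0.00837, 0.0564 without control 10) and secreted hepatocyte proteins (-0.13, adjusted p = 0.033, 0.212 without control 11 and 0.346 without tumour 81). These 4 had adjusted p = 0.505, 0.505, 0.216 and 0.507 with an estimated correlation. Peroxisome proliferator genes (median 0.08, adjusted p = 0.0282) missed without control 10 (0.284), tumour 93 (0.18), tumour 121 (0.104), tumour 124 (0.0865) or tumour 81 (0.0569). Neutrophil markers (median -0.31, adjusted p = 0.0276) missed without tumour 121 (0.0723) or tumour 124 (0.0656), and without control 10, high in inflammatory genes, the median turned to 0.089 (adjusted p = 0.571). The last 2 lists had adjusted p = 0.604 and 0.507 with an estimated correlation.

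Among lists that did not pass against control, the endothelial one (median -0.22, adjusted p = 0.649) again held 4 members that rose, such as Emcn (1.72, SE 0.38), and 6 that fell, such as Clec4g (-2.33, SE 0.79). The Kupffer cell and macrophage list (median -0.04, adjusted p = 0.74) held 4 members that fell (Clec4f -2.30, SE 0.69; Marco -2.13, SE 0.49; Timd4 -1.71, SE 0.47; Cd163 -1.23, SE 0.31), and 3 that rose (Gpnmb, Cd9 and Ms4a7). Control 10 was the array highest in this list, and without it the differences were -1.43 for Clec4f (adjusted p = 0.0938 over the list alone), -1.23 for Marco, -0.87 for Timd4 and -0.72 for Cd163. Bile acid genes had a median of -0.74 (adjusted p = 0.0637; 1 rose, Abcc4) and periportal genes -0.34 (0.0881; Hal fell and Apoc2 rose). The medians were, with the adjusted p, interferon-stimulated genes 0.32 (0.076), cholesterol synthesis 0.12 (0.142), fatty acid synthesis -0.14 (0.649), and acute phase genes -0.09 (0.274). They were for B and plasma cell markers -0.08 (0.285), T and NK cell markers 0.01 (0.724), erythroid markers -0.18 (0.219; Tfrc rose and Alas2 fell), pancreas, adipose and muscle markers 0.12 (0.123; 1 rose, Actg2) and the destruction complex -0.05 (0.739; 1 fell, Axin1).

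**Figure D3:**
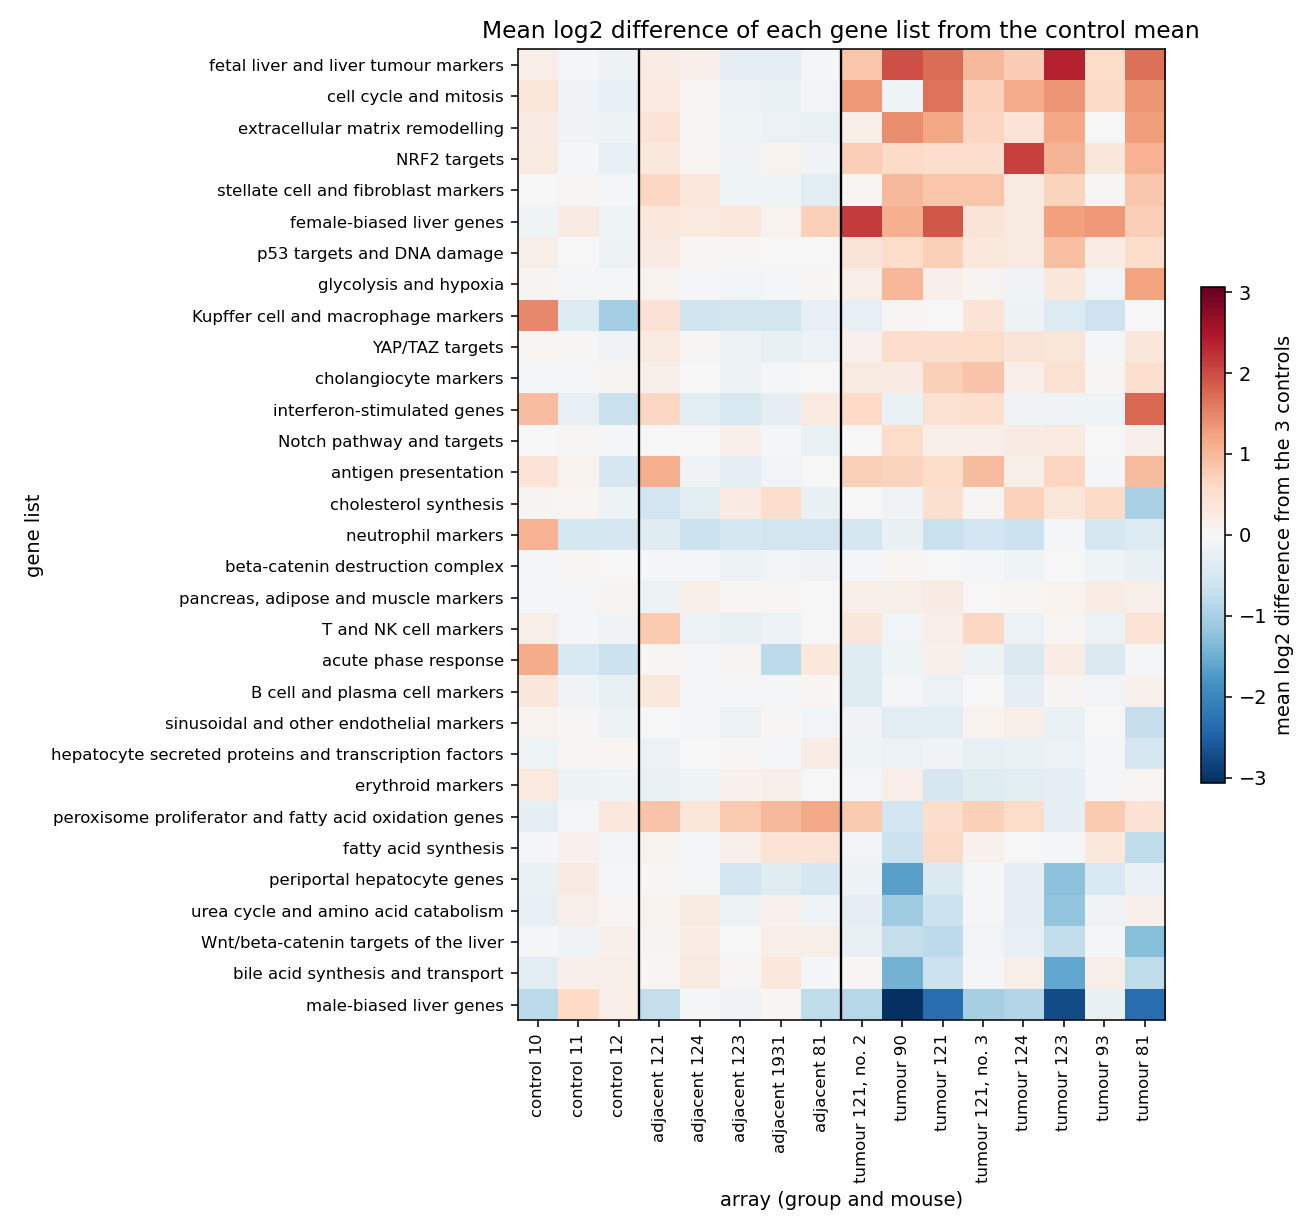
Mean log2 difference of each gene list (y axis) from the mean of the 3 controls, on each of the 16 arrays (x axis), red where higher and blue where lower. Among the tumours the male-biased list ran from -3.06 in tumour 90 to -0.22 in tumour 93, and the fetal liver and liver tumour list from 0.56 in tumour 93 to 2.36 in tumour 123.

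The 3 tumours of mouse 121 were compared with tumours of different mice. The SD of the difference between a pair of tumours averaged 0.45 log2 units over all genes within mouse 121 (3 pairs, 0.41 to 0.49) and 0.55 between mice (25 pairs, 0.38 to 0.69), so pairs within the mouse lay inside the range of pairs between mice. The closest pair of all arrays was the adjacent liver of mouse 121 and its tumour 3 (r = 0.990 across genes).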

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

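In 216 sets of 5 or 6 mice (a named gene or a list in 1 group), 19 values lay far from the others of their group by Dixon's test, several of them from the same mouse, where chance gives about 1 in 20 sets; no explanation was tested for these values.

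Several stand-out values came from single tumours. Tumour 123 had Afp at 9.23, where the other tumour mice had 5.24 to 6.04. Tumour 81 was low in Alb (11.89, others 12.39 to 12.58), high in the hexokinase Hk2 (7.10, others 4.17 to 5.08) and in Isg15 (7.30, others 4.02 to 5.09), and its interferon-stimulated list lay 1.76 above the control mean (others -0.21 to 0.52). Its hepatocyte secreted protein list lay at -0.52 (others -0.20 to -0.042). Tumour 90 was low in the proliferation genes Mki67 (4.57, others 5.97 to 6.62) and Top2a (3.85, others 5.61 to 6.52) and in Cpt1a (8.44, others 8.94 to 9.19). Tumour 124 was high in Gclc, which encodes a subunit of the enzyme that starts glutathione synthesis (11.37, others 9.46 to 10.09). The averaged tumours of mouse 121 were high in the sulfotransferase Sult2a1 (5.62, others 2.57 to 3.06). Tumour 93 had the lowest YAP/TAZ list mean, -0.059, where the other tumour mice lay at 0.34 to 0.55.

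Among adjacent livers, that of mouse 121 was high in Cd3e, a T cell receptor subunit (5.90, others 4.35 to 4.66), in the B cell gene Cd79a (3.27, others 2.65 to 2.70), and in the lists of T and NK cell markers (0.79, others -0.22 to -0.0077), antigen presentation (1.10, others -0.30 to -0.0030) and p53 targets (0.25, others 0.019 to 0.055). The adjacent liver of mouse 124 was high in Arg1 (10.96, others 10.69 to 10.74) and Krt19 (4.50, others 3.96 to 4.10).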

How the results depend on the processing

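Directions of the calls held in nearly all settings, while counts of genes moved widely. Control 10 was singled out after the data were seen, although the same fit without it was also among the planned omissions. The cause of a moved count was not tested, except where fewer genes or samples are its construction. For tumour against control the count of 6 became 35 without dim genes (12864 tested), 3 without an intensity trend, 31 with 8 tumours as separate values, 33 with the unnumbered tumour of mouse 121 only, 24 with the random replicate block, 10 without control 10, and 0 to 242 with 1 mouse left out. For tumour against adjacent liver the count of 36 became 22 with quantile normalization and 16 with median centring on top, 181 without dim genes, 136 with array weights, 8 with only the 2 groups, 87 with 8 tumours, 157 with the unnumbered tumour, 206 with the random and 0 with the fixed replicate block of paired mice (3145 at an unadjusted p under 0.05), 15 without control 10, and 5 to 743 with 1 mouse left out. For adjacent liver against control the count of 0 became 1 without control 10 and 0 to 1 with 1 mouse left out; every other setting gave 0.

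The 18, 21 and 4 lists past the threshold became 0, 0 and 0 with an estimated correlation and 2, 4 and 0 with fry. In adjacent liver against control the list count was also 2 without dim genes, 8 with only the 2 groups, 7 without control 10 and 2 to 7 with 1 mouse left out. The neutrophil list turned against control from a median of -0.31 to 0.089 without control 10 (-0.56 to 0.089 with 1 mouse left out, adjusted p up to 0.571). With the random replicate block 19, 21 and 3 lists passed, and with the fixed block of the 4 paired mice 19 passed for tumour against adjacent liver. With the fixed block none of the 11 named genes past the threshold in that comparison passed, and with the random block Glul and Axin2 passed as well. The SD of the difference among tumours of mouse 121 was 0.45 over all genes and 1.33 over the 1000 most variable, against 1.71 between mice. Genes near the lower end of the values carry little signal over background, and their changes are compressed.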

Other observations

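Tests on control 10 and the Wnt list, and those on tumour 93 except the first test of dilution, were chosen after the results were seen; the counts of splits were planned.

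The tumours differed from one another in genes that the group comparisons average out; the genes in this paragraph were chosen after their values were seen. Gpc3, glypican-3, was at 10.39 in tumour 123 and 7.76 in tumour 90, but at 3.01 in tumour 81 and 3.25 in tumour 93, within the range of non-tumoral livers (2.95 to 3.68). H19 was at 9.19, 9.72 and 9.44 in tumours 90, 123 and 81 and at 4.30 in tumour 124, and Igf2, its imprinted neighbour, was at 6.83 and 6.23 in tumours 123 and 81 but at 4.97 in tumour 90. Cyp4a12a, a male-specific fatty acid hydroxylase, was at 2.88, 4.94 and 3.55 in tumours 90, 123 and 81, and at 9.84 and 8.95 in tumours 124 and 93, near the controls (8.92 to 9.02). Within mouse 121 it was at 4.68 in the unnumbered tumour and at 9.16 and 8.95 in tumours 2 and 3. Cyp2b9, a female-biased gene, was at 9.06 in tumour 93 and 9.50 in tumour 90 but at 3.73 in tumour 81. Glul ran from 7.98 in tumour 81 to 10.79 in tumour 3 of mouse 121 and 10.76 in tumour 93.

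Regrouping the same mouse values gave the following. For tumour against adjacent liver, 100 of the 462 possible splits were used, the real one included. Of these, 2 gave as many genes as the real 36 and 4 as many lists as the real 21. Such shares are rare when values are exchanged freely, but this exchange ignores that 4 mice gave both tissues. The shares therefore do not exclude chance under the paired design. The most genes in another split were 65, with tumour 90 moved to the adjacent side, and the most lists, in a different split, were 23. Of the 6 drawn splits that part all 4 pairs, the real one included, 2 gave as many genes and 2 as many lists. So few splits cannot give a share under 0.05, so this count decides nothing. That limit lies in the draw, since further such splits among the 462 were not used. Splits that part fewer pairs gave at most 1 gene and 23 lists. For tumour against control, 8 of 84 splits gave as many genes as the real 6 and 15 of 84 as many lists as the real 18 (highest other 21), so chance cannot be excluded. The highest other split gave 1311 genes by setting tumours 90, 123 and 81 against the other tumours and the controls, and the next gave 193 with tumours 121, 90 and 123 set apart. Tumours 90, 123 and 81 lay lowest on the first principal component (-57.7, -56.2 and -43.9), furthest from the livers. The splits therefore do not tell a separate structure among the tumours from a graded distance to liver, and neither was tested. For adjacent liver against control, 49 of 56 splits gave as many lists as the real 4 (highest other 16), so chance cannot be excluded for the lists. With a real count of 0 genes all 56 splits give as many by construction (highest other 1), which decides nothing.

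Tumour 93 lay close to the non-tumoral livers, and its tests depended on the genes chosen and, for dilution, on the reference tissue. The first test of dilution with surrounding liver, on 18 genes that part the other tumours from control liver, argued against it. The share of the shift from control was 22.7% in 11 genes higher in tumours and 66.0% in 7 lower ones (difference -43.3, bootstrap SE 17.6). A second test was set up after that result. It took 743 genes that part the other tumours from adjacent liver and measured the shift from adjacent liver. Its shares were 22.3% and 19.8% (difference 2.44, bootstrap SE 3.17), close to each other, which dilution allows. An array of non-tumoral liver only, or exchanged with one, is spoken against by Scd2 (7.44, other tissues at most 5.73) and Wfdc3 (6.59, at most 4.61), and by other named genes such as Fkbp11 (8.58, at most 7.21) and Cbr3 (6.10, at most 4.51), but the rule that named them takes only genes whose tumours, tumour 93 among them, lie apart. On the 18 genes tumour 93 reached 51.1% of the shift and the highest adjacent liver 39.6% (SD 17.3), which excludes neither; on 242 genes chosen later the values were 36.0% and 30.3% (SD 11.5), of which the second by itself speaks against an exchange, although the spread of the adjacent livers entered the choice of these genes. Gene by gene, tumour 93 lay on the tumour side of all adjacent livers in 6 of the 18 genes, adjacent 121 lay so against the other adjacent livers in 11, and at most 33.3% of the genes of an adjacent liver lay nearer to the tumours. On the 242 genes these values were 91, 126 and 26.0%, of which the last again speaks against an exchange, with the same limit on the choice of genes. In both gene sets tumour 93 had to pass all adjacent livers, adjacent 121 included, whereas adjacent 121 had to pass only the others. The 2 counts were thus on unequal terms and cannot decide whether the array held non-tumoral liver only. All 3 explanations were left open for these reasons, and no biological one was tested.

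Control 10 was high in inflammatory genes: Cxcl13 was at 11.21, where the other 15 arrays lay at 4.62 to 6.48, and the Kupffer cell and macrophage list lay 2.67 above the other controls, interferon-stimulated genes 1.21 and neutrophil markers 1.09. Added blood or immune cells with unchanged hepatocytes are argued against by acute phase genes that hepatocytes make, which were higher by a median of 1.09 (20 genes; the other controls differed by 0.21). Whether the array holds liver of a deleted mouse cannot be told apart from this gene alone: Axin1 (5.07) lay 0.258 above the highest deleted array, where deleted arrays have an SD of 0.27. An inflamed control animal may be the source, as a hypothesis that no label bears on.

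Liver Wnt targets were lower in tumours although Axin1, which limits the pathway, was deleted. A lower share of hepatocytes could lower them too, and cannot be told apart: 11 hepatocyte genes of moderate level had a median of -0.411 (resampling SE of its distance from 0.5 times the Wnt median 0.155), against -0.52 for the Wnt list. These 11 are the members of the list of hepatocyte secreted proteins and transcription factors with an adjacent mean under 11. The whole list of 22 had a median of -0.10, so the fall in hepatocyte genes depends on the members taken. A loss of zoned genes of both zones alike also stays open, since the periportal list had a median of -0.363 with members going both ways.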
